A study of Mus musculus with 4 samples.

How the data were processed

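RNA from endometriotic lesions was hybridised to Affymetrix 3′ expression arrays, 2 for each diet. Per the labels' protocols, total RNA was isolated with a kit for small samples, 0.1 µg was used as input, and biotin-labelled aRNA was made by in vitro transcription. The deposited values are probe set intensity values on a linear scale, normalised between arrays by the authors. Per the submitters' processing notes, GCOS and RMA were used, and their versions, roles and order are not given in the sources used here. RMA usually returns log2 values and the design had assumed these, but the table was linear, so log2 was taken with no pseudocount before any test. The steps that led from RMA to linear values are not given, nor are detection calls, scan dates or slides, so no background call or batch could be used. Normalising between arrays makes the overall levels alike, so a shift shared by most genes would not be visible.

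Probe sets were named through the platform's gene annotation. Apart from 64 control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were used. The gene identifiers of 34741 probe sets matched the mouse reference gene table (GRCm38.p6), and 0 symbols were changed by it. No coordinates are given, because no genome build is named for the table. For each of 18193 genes the probe set with the highest mean was kept, and 12797 genes with a mean at or above the 40th percentile of all non-control probe sets (intensity 33.9) were tested.

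Groups were taken from the sample titles. The contrast was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment over all genes (1.80 prior and 3.80 total degrees of freedom). Differences are log2 of high-fat diet minus casein diet with the moderated standard error (SE) and a 95% interval. Of 42 gene lists fixed before the data were examined, 41 had at least 5 tested genes. They were tested by camera with a preset correlation of 0.01, with a correlation estimated for each list, on ranks, and by fry, each adjusted over the lists. Genes are named by a rule fixed beforehand: the 10 largest differences in each direction among genes that passed and did not overlap between groups, filled, since none passed, from genes with an unadjusted p under 0.01; up to 4 members of each list with the smallest p; and a fixed set of redox, inflammatory, hormonal and tissue genes. Unnamed gene models were counted but not named (4 candidates). The fixed genes Il6, Esr2 and Lep were not among the genes tested. The antioxidant, fatty acid oxidation, ovarian and hypoxia lists had a median, mean or camera direction that differed in sign, and none of these lists was called.

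The gene test was checked on 20 simulated data sets of 12797 independent genes, with 200 changed by known folds. With each gene's raw pooled spread, the first version of this check, 33.8%, 69.6%, 81.2% and 87.8% of genes changed 2-, 4-, 8- and 16-fold were recovered, with a mean of 5.8 false calls. With limma's moderated spread, adopted after that result was seen, 51.7%, 90.9%, 96.1% and 98.1% were recovered, with 12.45 false calls. Variation shared by many genes of an array, such as a mixture of tissues, was not simulated. The moderated spread is already drawn toward a common value, and the 200 planted changes themselves ease the adjusted threshold. The shares recovered therefore do not carry over to the real arrays, and a lack of called genes there does not argue against true changes. For 5 lists shifted by 0.5 log2, camera called 100% with the preset correlation and 40.0% with an estimated one, and 3.75% and 0% of the other lists. In this list check every gene had the median spread and genes were independent. Its rate of false calls therefore does not carry over to lists whose genes are correlated.

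Alternatives were the replicate number as a block, quantile normalisation, median centring, other filters, other choices of probe set, pseudocounts of 1 and 16, array weights, other variance priors, all probe sets, a threshold of 0.10, other list tests, and leaving out each array. After the data were examined, 2 more were added: casein diet replicate 2 against high-fat diet replicate 2 alone, and the fit without gastric, skeletal muscle and intestinal genes. Figures were drawn with matplotlib 3.10.9.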

Results

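Gene expression was measured in endometriotic lesions of mice on 4 arrays, 2 from mice given a high-fat diet and 2 from mice given a casein diet, which the labels call the control. Endometriotic lesions are growths of uterine-lining tissue outside the uterus. The series title places the comparison in the context of redox and inflammatory status, and the design implies 1 contrast, high-fat diet minus casein diet. Each array held 45101 probe sets, of which 12797 genes with a single gene symbol and a mean intensity of at least 33.9 were tested. The deposited median intensity was 55.1 and 56.5 for the casein diet and 56.4 and 56.1 for the high-fat diet. The number of arrays limits the precision, and nothing says how many animals or lesions each array represents, so limma's p-values for single genes measure only the spread between these samples. With 2 arrays against 2, the smallest exact two-sided permutation p is 0.333, so single values were tested only within limma's model across all genes.

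Among genes with an unadjusted p under 0.01 and groups that did not overlap, Mmp13, Slpi and Cd5l had the largest differences toward the high-fat diet, and Gkn2, Gkn1 and Tff1 toward the casein diet, but no gene passed limma's test after Benjamini-Hochberg adjustment at 0.05 (0 of 12797, smallest adjusted p = 0.823) or at 0.10. At an unadjusted p under 0.05 there were 636 genes, 287 higher and 349 lower on the high-fat diet, against 639.85 expected by chance. Both arrays of one diet lay above both of the other for 4602 genes, or 36.0%, where chance gives 33.3%. Of these, 106 were higher and 206 lower by more than 2-fold. Casein diet replicate 1 alone exceeded each other array by at least 1 log2 for 280 genes, against 14 for casein diet replicate 2. The larger count of lower genes therefore cannot be told apart from the distance of that array. The genes named by size of difference come from those with an unadjusted p under 0.01 and groups that did not overlap (57 higher, 79 lower). Genes with larger differences but a larger p, such as Myh1 of skeletal muscle (5.35, SE 2.60), are not among them. The difference of Myh1 came mostly from high-fat diet replicate 1, with an intensity of 4311 against 30.8 in high-fat diet replicate 2.

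Among those genes with larger values on the high-fat diet, Mmp13, an interstitial collagenase, differed most, by 3.66 on the log2 scale (SE 0.40, 95% interval 2.52 to 4.79). Its intensities were 38.9 and 63.2 on the casein diet and 831.2 and 470.6 on the high-fat diet. Slpi, a secreted inhibitor of leukocyte proteases, had the smallest p of all genes (log2 difference 3.09, SE 0.16, unadjusted p = 6.4e-05, adjusted p = 0.823). Its intensities were 532.5 and 683.6 on the casein diet and 4956 and 5294 on the high-fat diet. Cd5l, a secreted macrophage protein, differed by 2.81 (SE 0.21), and Saa3, an acute-phase apolipoprotein, by 2.46 (SE 0.19). Apoc2, the activator of lipoprotein lipase, differed by 2.20 (SE 0.18). Car3, a carbonic anhydrase abundant in fat and skeletal muscle, differed by 2.47 (SE 0.42), with 7414 in high-fat diet replicate 1, where skeletal muscle genes were also high, and 3467 in replicate 2. The collagenase gene Mmp8, the stromelysin gene Mmp3, the granzyme gene Gzmc and Lrrn1 differed by 2.31, 1.95, 1.87 and 1.86.

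Genes of the gastric mucosa had the largest values in the opposite direction, and they were uneven within the casein diet. Gkn2, which encodes a gastrokine secreted by stomach surface cells, had intensities of 14933 and 2548 on the casein diet and 22.3 and 17.4 on the high-fat diet (log2 difference -8.29, SE 0.94). The differences were -7.42 for Gkn1, -5.89 for the trefoil factor gene Tff1 and -5.01 for Gkn3. Ido1, which encodes a tryptophan-degrading enzyme, differed by -3.06 (SE 0.57), and Cftr, a chloride channel gene of epithelia, by -2.53 (SE 0.40). The remaining genes of this rank were Upk3b of mesothelium (-2.43), the membrane mucin gene Muc4 (-1.84), the phospholamban gene Pln (-1.76) and the kinase gene Pak3 (-1.67). Without casein diet replicate 2, which leaves casein diet replicate 1 as the only array of that diet, Gkn1, Gkn2, Gkn3 and Tff1 differed by -8.9, -9.6, -6.4 and -7.0. Without casein diet replicate 1 they differed by -5.9, -7.0, -3.6 and -4.8.

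**Figure D1:**
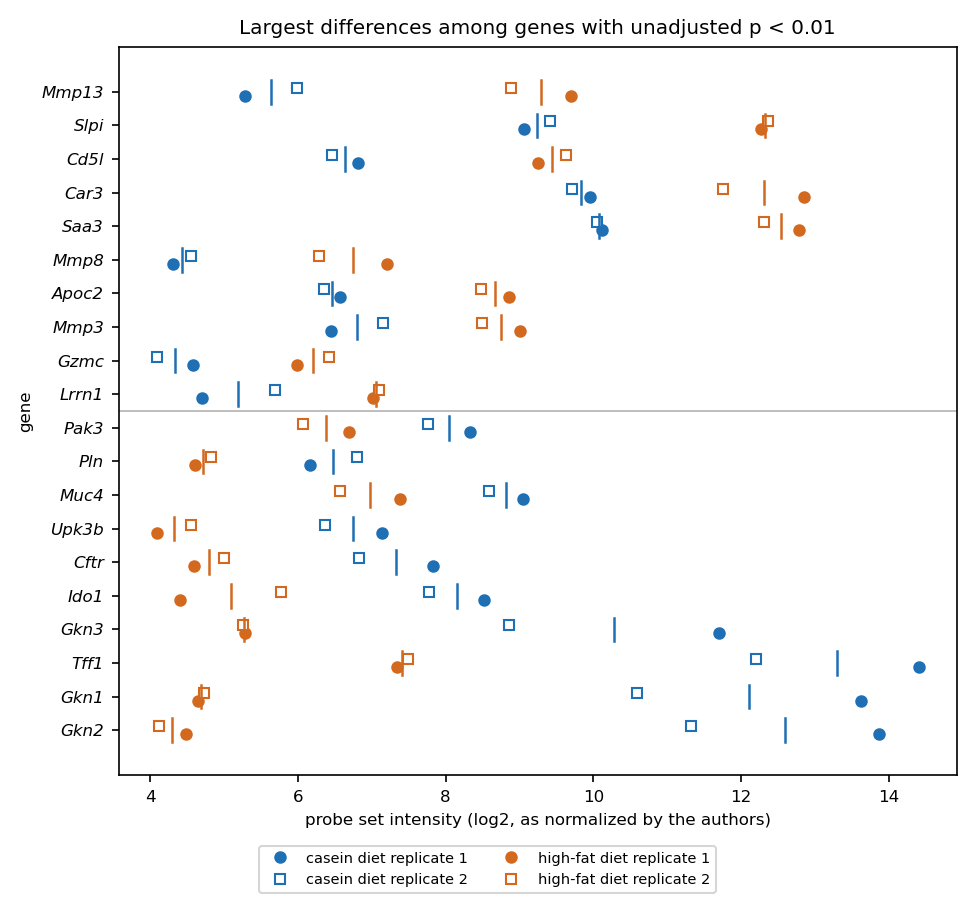
Probe set intensity (log2, horizontal axis) of the 20 genes with the largest differences among those with an unadjusted p under 0.01 and groups that did not overlap, as 1 point per array and a vertical bar at each diet's mean of 2 arrays. The 2 diets do not overlap for any of these genes, and the 4 lowest ones (Gkn1, Gkn2, Gkn3, Tff1) are spread widely between the casein diet arrays.

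The arrays did not fall into diets by similarity. Casein diet replicate 2 correlated more closely with high-fat diet replicates 1 and 2 (r = 0.961 and 0.976 across tested genes, which are not independent replicates) than with casein diet replicate 1 (r = 0.954). Casein diet replicate 1 lay at -46.3 on the first principal component, which held 61.5% of the variance, and the other arrays lay between 0.04 and 30.2. It exceeded each other array by at least 1 log2 for 280 genes, against 14, 77 and 60 genes for casein diet replicate 2, high-fat diet replicate 1 and high-fat diet replicate 2. Besides gastric genes, it was also highest for some intestinal and pancreatic markers, with intensities of 391.7 for Vil1, 1908 for Lgals4, 475.0 for Zg16 and 1443 for Cela1, against at most 30.7, 139.0, 48.7 and 215.4 in the other arrays. Other named members of the intestinal and pancreatic lists stood out less. The high-fat diet minus casein diet replicate 1 was -1.43 for Apoa1, -0.53 for Ctrl, -0.13 for Anpep and 0.08 for Ctrb1. Most markers of these 2 lists were too dim to test: only 9 of 26 intestinal and 9 of 21 pancreatic genes on the array reached the filter. The intestinal list (7 of 9 lower) and the exocrine pancreas list (8 of 9 lower) had mean deviations of 0.77 and 0.72 there and were not called (camera adjusted p = 0.132 for each), but both were called lower without casein diet replicate 2. Skeletal muscle genes stood out in high-fat diet replicate 1, where Ttn, the gene of the sarcomere protein titin, had an intensity of 4053, against 43.6 in high-fat diet replicate 2 and 19.2 and 16.7 on the casein diet. The 3′ minus 5′ difference of Gapdh, a measure of RNA integrity, was 1.03 and 1.09 log2 on the casein diet and 1.19 and 0.98 on the high-fat diet.

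**Figure D2:**
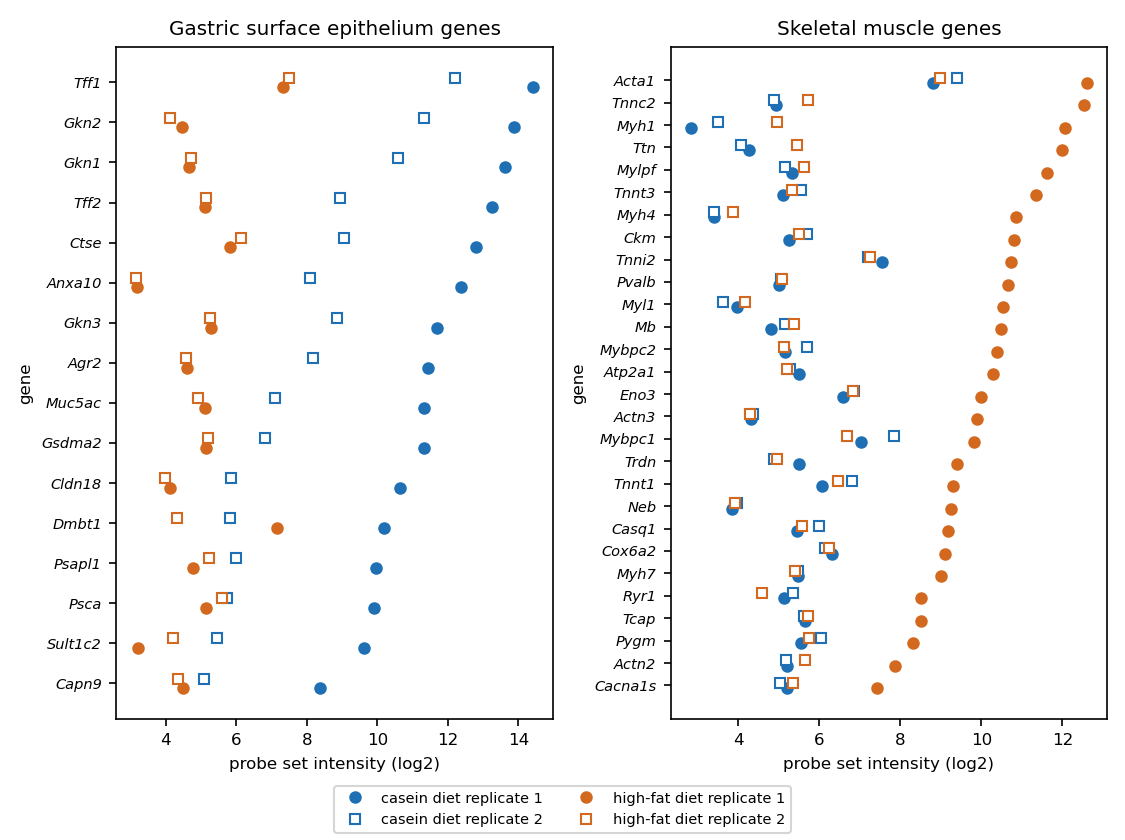
Probe set intensity (log2, horizontal axes) of 16 genes of the gastric surface epithelium and 28 skeletal muscle genes, 1 point per array. Gastric genes are highest in casein diet replicate 1, and skeletal muscle genes are highest in high-fat diet replicate 1.

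Gene lists fixed before the data were examined were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01. This preset treats the genes of a list as nearly independent, so its p-values rest largely on the spread over genes, not between samples. The correlation estimated from these arrays reached 0.99, for skeletal muscle markers. Of 41 lists with at least 5 tested genes, 19 passed at an adjusted p under 0.05, 7 higher and 12 lower on the high-fat diet. None passed with a correlation estimated from these arrays (lowest adjusted p = 0.610), and fry, which asks whether a list's genes move one way, called 0 (smallest unadjusted p = 0.0327, adjusted p = 0.579). Its mixed test, which asks for change in either direction, called 1 list, mesothelium markers (unadjusted p = 0.00115). With the preset correlation, splits of the arrays that mixed the diets gave 13 and 16 called lists, against 19 for the diets. No list member passed over all genes tested, so members are given as values. Of 182 named genes, 92 moved by over 1.5 times when 1 array was left out. Casein diet replicate 1, the array with the highest gastric genes, lay farthest from the 4-array mean for 14 of the 19 called lists. For the called lists, counts adjusted over the list alone are given where they exceeded 0.

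Genes of lipid uptake and lipid droplets shifted higher, with 25 of 31 above the casein diet and a median of 0.34 (camera adjusted p = 7.66e-06, adjusted p = 0.610 with an estimated correlation). The cholesterol exporter genes Abcg1 and Abca1 differed by 0.95 (SE 0.10) and 1.09 (SE 0.28, 0.72 without casein diet replicate 1), the fatty acid-binding protein gene Fabp4 by 1.47 (SE 0.31) and Apoe by 0.72 (SE 0.17). Abcg1, Abca1 and Apoe act in cholesterol efflux and transport. In this list 1 gene passed when adjusted over the list alone. Genes of cholesterol synthesis shifted lower, all 20 with smaller values on the high-fat diet and a median of -0.57 (camera adjusted p = 9.52e-08, adjusted p = 0.610 with an estimated correlation). Fdps and Msmo1 differed by -1.36 (SE 0.48) and -1.20 (SE 0.42), or -0.72 and -0.64 without casein diet replicate 1 and -2.00 and -1.76 without casein diet replicate 2, and 0 passed when adjusted over the list alone. The mean deviation of the cholesterol list was 0.68 in casein diet replicate 1 and -0.04 in casein diet replicate 2, against -0.39 and -0.25 on the high-fat diet. Without casein diet replicate 1 its median was -0.28 and without casein diet replicate 2 it was -0.98, and the median of the lipid uptake list was 0.20 without casein diet replicate 1 and also 0.20 without high-fat diet replicate 1. The lists of fatty acid oxidation (12 of 27 higher), fatty acid synthesis (14 of 19 lower) and adipocyte markers (13 of 20 higher) were not called, with camera adjusted p = 0.506, 0.104 and 0.0888. Fatty acid synthesis was called lower without high-fat diet replicate 2, and adipocyte markers were called higher in 3 alternatives, 1 of them without high-fat diet replicate 1. The adipokine gene Adipoq had intensities of 106.9 and 91.4 on the casein diet and 33.1 and 348.1 on the high-fat diet.

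Redox genes did not move together. Antioxidant enzymes were divided evenly, 21 higher and 21 lower, with a median of -0.003 (camera adjusted p = 0.625). Within this list Gpx3, the secreted glutathione peroxidase, had intensities of 2408 and 2107 on the casein diet and 4900 and 6080 on the high-fat diet, a log2 difference of 1.28 (SE 0.16, unadjusted p = 0.00163, adjusted p = 0.849). The selenium transport protein gene Selenop differed by 0.41 (SE 0.12) and the epithelial glutathione peroxidase gene Gpx2 by -0.86 (SE 0.23). Cat and Sod2, for catalase and the mitochondrial superoxide dismutase, differed by 0.24 (SE 0.17) and 0.30 (SE 0.19), or by 0.07 to 0.42 and 0.12 to 0.48 when 1 array was left out. Targets of NRF2, a transcription factor of the oxidative stress response, shifted lower (18 of 24, median -0.21, camera adjusted p = 0.0111, adjusted p = 0.610 with an estimated correlation). That call was lost without casein diet replicate 1 (median -0.05, adjusted p = 0.181) and without high-fat diet replicate 2 (median -0.19, adjusted p = 0.126). Its mean deviation was 0.43 in casein diet replicate 1, where gastric genes were also highest, and -0.04, -0.20 and -0.20 in the other arrays. Its largest named difference, -2.57 for Nqo1 (SE 1.30), came with intensities of 895.2 and 76.6 on the casein diet and 51.0 and 38.3 on the high-fat diet. Neither genes of reactive oxygen species production (9 of 16 higher, adjusted p = 0.132) nor glutathione S-transferases (11 of 19 lower, adjusted p = 0.118) were called by the main test, and Nox4 differed by 0.52 (SE 0.31), or by 0.18 to 0.86 when 1 array was left out. The glutathione S-transferase genes Gsta4 and Mgst2 were likewise high in casein diet replicate 1, at 5433 and 1715 against at most 599.0 and 225.5 in the other arrays. The list of reactive oxygen species production was called higher without high-fat diet replicate 2 (median 0.17, adjusted p = 0.0382), and that of glutathione S-transferases lower without casein diet replicate 2 (median -0.38, adjusted p = 0.00126).

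T and NK cell markers shifted lower, 25 of 28 with a median of -0.42 (camera adjusted p = 1.76e-06, adjusted p = 0.610 with an estimated correlation). Ccr7, the lymph-node homing receptor, differed by -1.24 (SE 0.18) and the T cell coreceptor gene Cd8a by -1.37 (SE 0.45). The intensities of Cd8a were 196.4 and 85.5 on the casein diet and 54.4 and 46.3 on the high-fat diet, and its difference was -0.77 without casein diet replicate 1. Class II antigen presentation genes shifted lower, 13 of 15 with a median of -0.43 (camera adjusted p = 8.23e-05, adjusted p = 0.610 with an estimated correlation), and 1 gene passed when adjusted over the list alone. Cd83 differed by -0.63 (SE 0.09) and H2-Eb1 by -0.47 (SE 0.23), the latter by -0.22 to -0.71 when 1 array was left out. Without casein diet replicate 1 the medians of these 2 lists were -0.18 and -0.17, and without casein diet replicate 2 they were -0.83 and -0.71. Cytokines and chemokines shifted lower, 31 of 44 with a median of -0.24 (camera adjusted p = 0.00362, adjusted p = 0.610 with an estimated correlation). Cxcl13, Ccl3 and Ccl4 differed by -0.77, -0.86 and -0.81, the last 2 by -0.53 and -0.52 without casein diet replicate 1, whereas the platelet factor gene Pf4 differed by 1.66 (SE 0.23), and the call was lost without high-fat diet replicate 2 (median -0.26, adjusted p = 0.0937). The median was -0.13 without casein diet replicate 1, where the call remained. Macrophage markers shifted higher, 23 of 32 with a median of 0.24 (camera adjusted p = 0.00244, adjusted p = 0.610 with an estimated correlation). Members went both ways, Lgmn by 0.87 (SE 0.21) and the scavenger receptor gene Cd163 by -1.06 (SE 0.10), and 3 genes passed when adjusted over the list alone. Without high-fat diet replicate 1 the macrophage call was lost (median 0.15, adjusted p = 0.0639). The median was 0.14 without casein diet replicate 1, 0.16 without casein diet replicate 2 and 0.40 without high-fat diet replicate 2. The cytokine genes Tnf and Ccl2 differed by 0.09 (SE 0.19) and -0.26 (SE 0.23). Adgre1, the F4/80 macrophage antigen, differed by 0.27 (SE 0.21), and the macrophage gene Cd68 by 0.51 (SE 0.29), with ranges of 0.04 to 0.50 and 0.15 to 0.88 when 1 array was left out. Ptgs2, the inducible cyclooxygenase, differed by -1.06 (SE 0.39), or by -1.58 without high-fat diet replicate 1 and -0.54 without high-fat diet replicate 2. Neutrophil and mast cell markers (12 of 15 higher, adjusted p = 0.101), complement (13 of 19 higher, adjusted p = 0.280) and prostaglandin genes (9 of 16 lower, adjusted p = 0.625) were not called, although the first of these was called higher in 2 alternatives and complement in 1.

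Several lists of tissue markers were called, but endometrial stroma markers were not (18 of 28 higher, median 0.32, camera adjusted p = 0.159). The stroma median was 0.01 without casein diet replicate 1, and without casein diet replicate 2 the list was called higher (median 0.55, adjusted p = 0.000777). Smooth muscle markers shifted lower, 20 of 22 with a median of -0.54 (camera adjusted p = 2.82e-12, adjusted p = 0.610 with an estimated correlation), and 9 passed when adjusted over the list alone. The contractile genes Cnn1, Actg2 and Tpm2 differed by -1.24 (SE 0.14), -1.26 (SE 0.15) and -0.77 (SE 0.09), and Acta2 by -0.41 (SE 0.13). Of 3 other probe sets of Tpm2 only 1 had the same sign, and the dimmest gave 0.00015. Endothelial markers shifted higher, 25 of 27 with a median of 0.37 (camera adjusted p = 5.10e-08, adjusted p = 0.610 with an estimated correlation). Cdh5, the endothelial cadherin, differed by 0.98 (SE 0.18) and the VEGF receptor gene Kdr by 0.76 (SE 0.20). Their median was 0.19 without casein diet replicate 1 and 0.21 without high-fat diet replicate 2. Matrix proteases shifted higher, 20 of 27 with a median of 0.38 (camera adjusted p = 8.23e-05, adjusted p = 0.610 with an estimated correlation), and Mmp13, Mmp8 and Mmp3 were the 3 members with the smallest p, and 3 genes passed when adjusted over the list alone. Their median was 0.16 without casein diet replicate 1, 0.63 without casein diet replicate 2 and 0.21 without high-fat diet replicate 1. Collagens and extracellular matrix genes shifted higher, 29 of 43 with a median of 0.18 (camera adjusted p = 0.00225, adjusted p = 0.673 with an estimated correlation), and that call was lost without casein diet replicate 1 (median -0.02) and without high-fat diet replicate 1 (median -0.04). The median was 0.34 without casein diet replicate 2 and 0.29 without high-fat diet replicate 2. Endometrial epithelium markers shifted lower, 29 of 35 with a median of -0.57 (camera adjusted p = 1.58e-05, adjusted p = 0.610 with an estimated correlation). Muc1, Cldn7 and Lcn2 differed by -1.31, -0.88 and -0.91, and 4 genes passed when adjusted over the list alone. The epithelial genes Krt18 and Epcam differed by -0.81 (SE 0.54) and -0.67 (SE 0.47), and Krt18 by -0.21 without casein diet replicate 1 and -1.42 without casein diet replicate 2. The epithelial call was lost without high-fat diet replicate 1 (median -0.04, adjusted p = 0.779), the array with the skeletal muscle genes, and Epcam had an intensity of 813.1 there and at least 1953 in the other 3 arrays. Without high-fat diet replicate 2 the epithelial median was -1.12. Mesothelium markers shifted lower, 10 of 16 with a median of -0.40 (camera adjusted p = 0.00188, adjusted p = 0.610 with an estimated correlation), although Slpi, a member, differed by 3.09 the other way, and 7 genes passed when adjusted over the list alone. The mesothelial call was lost with a 60th percentile filter, where the median was 0.07. Skeletal muscle markers shifted higher, 28 of 28 with a median of 2.16 (camera adjusted p = 2.86e-07, adjusted p = 0.655 with an estimated correlation). Without high-fat diet replicate 1 the skeletal muscle median was 0.01 and the call was lost (adjusted p = 0.104), and without high-fat diet replicate 2 it was 4.55. Nerve and Schwann cell markers (9 of 13 lower, adjusted p = 0.104) and ovarian markers (9 of 14 lower, adjusted p = 0.661) were not called, although the former were called lower in 2 alternatives.

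**Figure D3:**
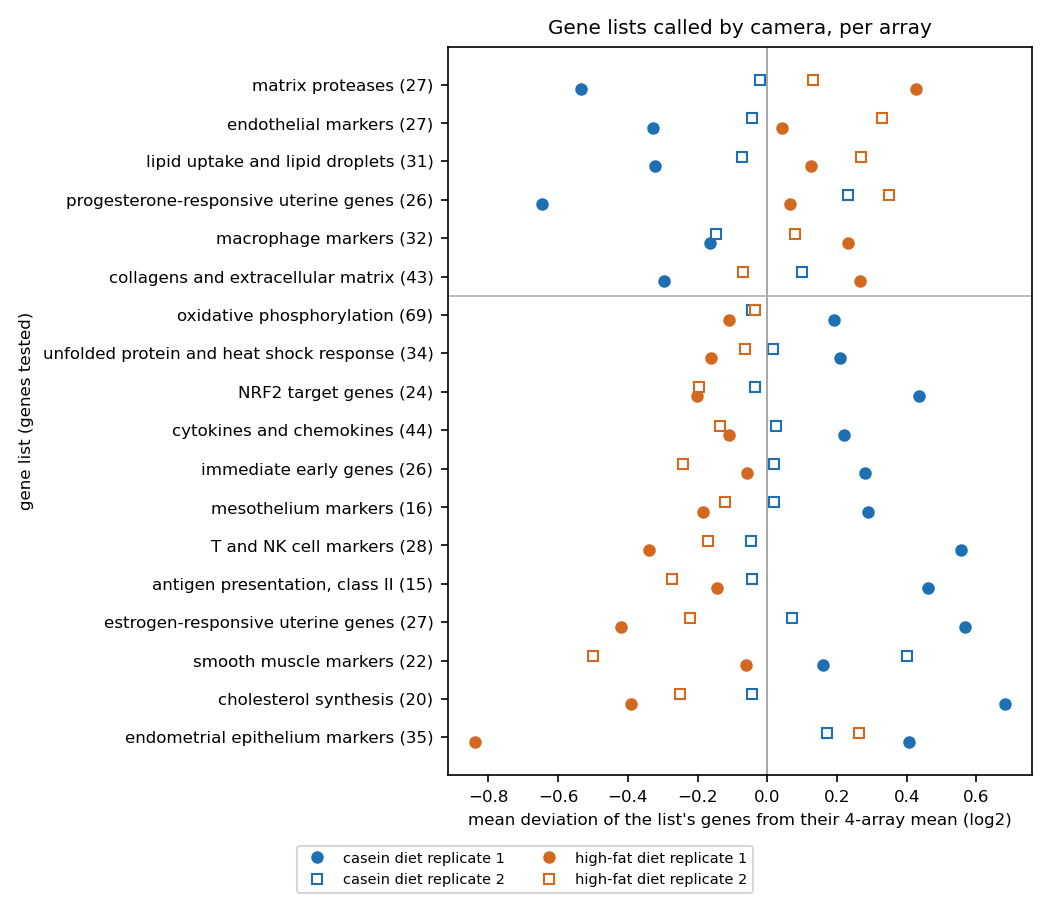
Mean deviation of each called list's genes from their mean over the 4 arrays (log2, horizontal axis), 1 point per array, for the called lists other than skeletal muscle, which would not fit the scale. Lists above the line were higher on the high-fat diet by camera, and casein diet replicate 1 is the most distant array for most of them.

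Hormone-responsive and stress-related genes were the last lists with calls. Estrogen-responsive uterine genes shifted lower, 22 of 27 with a median of -0.43 (camera adjusted p = 9.41e-05, adjusted p = 0.610 with an estimated correlation). This list holds Tff1, Muc1 and Lcn2 and shares 5 genes with the epithelial list, 3 genes passed when adjusted over the list alone, and its median was -0.12 without casein diet replicate 1. Progesterone-responsive uterine genes shifted higher, 20 of 26 with a median of 0.28 (camera adjusted p = 0.0163, adjusted p = 0.655 with an estimated correlation), and that call was lost without casein diet replicate 1 (median 0.003) and without high-fat diet replicate 2 (median 0.24, adjusted p = 0.164). The median was 0.79 without casein diet replicate 2 and 0.47 without high-fat diet replicate 1. Esr1 and Pgr, the estrogen and progesterone receptor genes, differed by -0.05 (SE 0.14) and -0.39 (SE 0.09), and the progesterone-responsive gene Klf9 by -0.41 (SE 0.12). Oxidative phosphorylation genes shifted lower by a small amount, 67 of 69 with a median of -0.14 (camera adjusted p = 1.76e-06, adjusted p = 0.655 with an estimated correlation), and that call was lost without casein diet replicate 1 (median -0.02, adjusted p = 0.621), and the median was -0.27 without casein diet replicate 2. Genes of the unfolded protein and heat shock response shifted lower, 27 of 34 with a median of -0.19 (camera adjusted p = 6.64e-05, adjusted p = 0.610 with an estimated correlation). The chaperone genes Hspa1b and Hspa1a differed by -1.07 (SE 0.22) and -0.97 (SE 0.25), the latter by -0.65 without casein diet replicate 1, and the list's median was -0.10 without casein diet replicate 1. Immediate early genes, which follow acute stimuli, shifted lower, 21 of 26 with a median of -0.25 (camera adjusted p = 0.000327, adjusted p = 0.610 with an estimated correlation), and that call was lost without high-fat diet replicate 2 (median -0.12, adjusted p = 0.126). The median was -0.08 without casein diet replicate 1, where the call remained. Nr4a3 and Nr4a2 differed by -0.86 (SE 0.16) and -0.99 (SE 0.27), the latter by -0.65 without casein diet replicate 1. Genes of estrogen metabolism and steroid receptors (10 of 15 lower, adjusted p = 0.104) and of cytosolic ribosomal proteins (26 of 42 lower, adjusted p = 0.964) were not called, although the former were called lower in 1 alternative.

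Of the 19 called lists, 10 remained called in each of the 4 fits that left out 1 array. They were T and NK cell markers, class II antigen presentation, smooth muscle, mesothelium and endothelium. The others were matrix proteases, estrogen-responsive genes, lipid uptake, cholesterol synthesis and the unfolded protein response. These fits share arrays and keep the preset correlation, so their p-values still rest largely on the spread over genes. Remaining called is therefore no evidence that a list differs by diet beyond the spread between samples. By the main test, cell cycle genes (32 of 40 lower, median -0.11, adjusted p = 0.194), interferon-stimulated genes (17 higher and 17 lower, adjusted p = 0.706) and hypoxia and angiogenesis genes (14 of 29 higher, adjusted p = 0.335) were not called. When 1 array was left out, cell cycle genes were called in both directions, higher without casein diet replicate 1 (median 0.13, adjusted p = 0.000343) and lower without casein diet replicate 2 (median -0.37, adjusted p = 3.37e-05) and without high-fat diet replicate 1 (median -0.25, adjusted p = 0.000109). Interferon-stimulated genes were likewise called higher without casein diet replicate 1 (adjusted p = 0.0211) and lower without casein diet replicate 2 (adjusted p = 0.00464) and without high-fat diet replicate 1 (adjusted p = 0.0457). Genes of Wnt, hedgehog and Notch signalling (28 of 39 higher, adjusted p = 0.0633) and the NF-kB pathway (17 of 25 lower, adjusted p = 0.0714) were not called by the main test, but each was called in that direction in 6 alternatives. Mki67, Vegfa and Hif1a differed by 0.13 (SE 0.33), -0.05 (SE 0.11) and 0.11 (SE 0.11), the last by 0.03 to 0.18 when 1 array was left out.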

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

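The added alternatives (casein diet replicate 2 against high-fat diet replicate 2, and the fit without gastric, muscle and intestinal genes) were chosen after the data were examined. The count of genes called by limma was 0 in the main fit and under each alternative except the fit without casein diet replicate 2, so it ranged from 0 to 17 over the fits without 1 array, where the lone array is assumed to vary like the other group. Genes at an unadjusted p under 0.05 numbered 431 to 1825 in those fits and 2264 over all 45037 probe sets, against 636. The count of called lists was 17 to 28 without 1 array, and 0 with an estimated correlation or by fry. It was 23 with the replicate number as a block, which called 0 genes (576 at an unadjusted p under 0.05). The deviations of the same-numbered arrays correlated at -0.022 over only 2 pairs, so the numbers are taken as names. Without gastric, muscle and intestinal genes, 18 of 39 lists were called. Of the 22 lists not called in the main setting, 16 were called in at least 1 alternative, 2 of them (cell cycle and interferon-stimulated genes) in both directions. Of 182 named genes, 172 had one sign in every setting. That count is no measure of robustness, because many of these genes were picked for non-overlapping groups or a small p. With non-overlapping groups, leaving out 1 array cannot change the sign.

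Camera's direction turned in no called list under any alternative fit, but 4 called lists had a median of the opposite sign in at least 1 comparison. Casein diet replicate 2 against high-fat diet replicate 2 alone, with no test, gave medians of -0.0080 for skeletal muscle, -0.239 for extracellular matrix and 0.028 for oxidative phosphorylation. The extracellular matrix median was also below 0 without casein diet replicate 1 (-0.024) and without high-fat diet replicate 1 (-0.039), and that of mesothelium was above 0 with the 60th percentile filter (0.072). Over the fits without 1 array, medians ranged from -0.027 to 0.035 for antioxidant enzymes, -0.187 to 0.097 for prostaglandin genes, -0.155 to -0.010 for NF-kB genes, -0.017 to 0.260 for complement, -0.148 to 0.087 for interferon-stimulated genes, 0.084 to 0.326 for B and plasma cells, -0.033 to 0.636 for neutrophils and mast cells, -0.066 to 0.225 for adipocytes, -0.105 to 0.017 for ovarian markers, -0.366 to 0.133 for cell cycle, -0.021 to 0.265 for Wnt, hedgehog and Notch, -0.077 to 0.093 for fatty acid oxidation and -0.074 to 0.042 for ribosomal proteins. With other choices, camera's direction turned for complement with the dimmest probe set (median 0.076). It turned for ovarian markers with no filter (-0.0014), the dimmest probe set (-0.033) and a pseudocount of 16 (-0.043). For ribosomal proteins it turned with the 60th percentile filter (-0.0059), the mean of probe sets (-0.0029) and the dimmest probe set (-0.0050). For interferon genes (-0.0094), fry gave the direction opposite to camera's. Among genes without 1 array, the ranges were -0.556 to 0.029 for Ccl2, -0.125 to 0.305 for Tnf, -0.191 to 0.095 for Esr1, -0.246 to 0.510 for Mki67, -0.147 to 0.049 for Vegfa, -1.58 to 1.82 for Adipoq, -0.455 to 0.0079 for Nusap1 and -0.344 to 0.094 for Rpl14. With the dimmest probe set, Cmpk2 was at -0.073 and Tpm2 at 0.00015. The mesothelium call was lost with the 60th percentile filter and the dimmest probe set (-0.377). Beyond the smaller number of samples or genes in some fits, the cause was not tested. No detection calls were used, so how far dim genes lie above background is not known.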

Other observations

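Tests in this part were chosen after the results were seen, except the test of large peritoneal macrophages and the counts of other splits, whose outcome had not been seen when they were written. An SE given here with a median over a gene list is the standard error over the list's genes. It does not measure the spread between arrays.

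B and plasma cell markers were not called as a list (10 of 16 higher, camera adjusted p = 0.101, 1 gene passing when adjusted over the list alone) except in 3 alternatives, but Mzb1, a chaperone of antibody-secreting cells, had intensities of 198.2 and 265.4 on the casein diet and 631.6 and 765.1 on the high-fat diet (log2 difference 1.60, SE 0.20). Among complement genes, Cfp and C5ar1 differed by 0.97 (SE 0.18) and 1.06 (SE 0.25), although Cfp was at 0.09 by its dimmest probe set, and Clu by -0.96 (SE 0.15). Pdk4, a kinase that restrains glucose oxidation, differed by 1.88 (SE 0.61), with 245.8 in high-fat diet replicate 1, the array with skeletal muscle genes, and 82.2 in replicate 2. The progesterone-responsive gene Il13ra2 had intensities of 31.9 and 118.0 on the casein diet and 369.9 and 261.3 on the high-fat diet. None of these passed after adjustment over all genes.

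Gastric surface genes in casein diet replicate 1, where some intestinal and pancreatic markers were also high, are the first pattern. All 16 genes of a gastric surface list exceeded the mean of the other 3 arrays there, by a median of 5.61 log2, and the median over 8 gastric endocrine genes was 1.58, with 6 higher and Hdc (-1.86) and Cck (-0.18) lower there, and over the 4 of them above the filter it was 2.40 (SE 1.22). Degraded RNA in that array does not account for it, because its 3′ minus 5′ differences lay 0 log2 outside the range of the other arrays. Whole stomach corpus wall stays open, because only 3 parietal and chief cell genes were tested, with a median excess of 0.0743 (SE 0.398), and over all 8 on the array, 5 of them below the filter, it was 0.0911 (SE 0.589), with Atp4a (25.4) and Atp4b (46.5) near their level in the other arrays and Cblif and Pgc higher by 3.44 and 1.99. One source of tissue shared with casein diet replicate 2 stays open too, since 56.25% of surface genes lay within a factor of 2 of the median share (4.38%, range 0.298% to 21.0%), and a gastric-type change of lesion epithelium, other stomach regions and an effect of diet were not tested.

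Skeletal muscle genes in high-fat diet replicate 1 are the second pattern. All 28 tested genes (100%) were at least 1 log2 higher there than in each other array, so muscle tissue in that sample is a candidate source. An effect of the diet as the whole cause is argued against, since the median of high-fat diet replicate 2 minus the casein diet mean was 0.0142 (SE 0.098) over the same genes. Endometrial epithelium genes were lowest in the same array, with a mean deviation of -0.84 against 0.26 in high-fat diet replicate 2.

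Higher Cd5l, Apoc2 and Abcg1 on the high-fat diet are the third pattern, and these 3 genes are known targets of the sterol-sensing receptor LXR. Whether more macrophages are the whole cause is not decided by 15 pan-macrophage genes. All 15 were higher, with a median difference of 0.270 (SE 0.064 over genes), below the 0.95 of Abcg1. Cd5l, Apoc2 and Abcg1 were named for a large difference or a small p. The median of genes not picked in this way would tend to lie lower whatever the cause. The 9 tested large peritoneal macrophage genes did not rise as a set, with a median of -0.263 (SE 0.279 over genes), below the 0.95 of Abcg1. This does not decide on the cells, because the genes ran from -1.18 for Gata6 to 1.43 for Tgfb2. Itgam is also in the pan-macrophage list and Icam2 in the endothelial list. Timd4 and Vsig4 were below the filter. Higher LXR activity may contribute, but 15 other targets had a median of 0.102 (SE 0.122, 9 higher), which was 0.067 to 0.333 without each array in turn, and camera gave an unadjusted p = 0.0022 with the preset correlation and 0.104 with an estimated one, so it stays open. The criterion written for this test, on camera with the preset correlation and the medians without each array, was met, but a median within its error of 0 over genes that go both ways decides nothing, and 5 of the targets belong to the called lipid list.

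Other splits cannot exclude chance here, because 4 arrays divide into 2 and 2 in only 3 ways. Camera called 19 lists for the diets and at most 16 for the other splits, so 1 of the 3 splits gave as many. Genes at an unadjusted p under 0.05 numbered 636 for the diets and at most 462 for the other splits, again 1 of 3.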
